A study of Mus musculus with 6 samples.

How the data were processed

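Messenger RNA was sequenced from whole mouse testes labelled day 9, in 3 control libraries and 3 libraries from mice with a germ-cell conditional knockout of Dcaf2. Per the labels' protocols, total RNA was purified with a column kit and libraries were made with a messenger RNA kit (Hieff NGS Ultima Dual-mode). The labels number the samples within each group but do not say whether each number is a separate animal, so p-values measure the spread between these samples, which can be partly technical.

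The authors deposited 1 table for the whole series, with a count and an FPKM value per gene and library. The submitters' processing notes name StringTie 1.3.1 and RSEM, without saying what each was used for. The aligner, the genome build, the annotation release and any use of strand are not given in the sources used here, so no coordinates are printed. The deposited counts are whole numbers. They were taken as estimated counts that the authors had rounded, since 3 to 21 genes per library had a count of 0 beside an FPKM above 0. They were used as deposited, without further rounding. The FPKM values that the authors deposited are scaled to transcript length and library size. They were used only in the check of the count columns, and no test was run on them.

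The table held 22274 Ensembl gene IDs. A symbol was found for 22219 of them in the reference table of gene names supplied with the data, and 55 IDs without a symbol kept their ID as name. The symbols in the deposited table were not used for naming, because 15249 were equal to the reference symbol and 1159 were given as a dash. Older names in the gene lists were looked up through the synonyms of the RefSeq gene table. Genes of multi-copy families share reads with near-identical copies, and their single values are uncertain.

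Totals ran from 15407007 to 18372964 counts per library. Genes were kept by filterByExpr of edgeR 4.0.16 at its default minimum count of 10, which left 14424 genes for testing. The genes left out held 0.063% of all counts. Counts were scaled by the trimmed mean of M values (TMM), and CPM values use these scaled library sizes. Genotype was tested with edgeR's quasi-likelihood test (glmQLFit and glmQLFTest, R 4.3.3), without covariates, and p-values were adjusted by the Benjamini-Hochberg method with a threshold of 0.05. The standard error (SE) of a log2 fold change is its size divided by the square root of the F statistic. Log2 fold changes are knockout against control, so a negative value is lower in the knockout.

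The 23 gene lists were fixed before the data were examined, and members that were tested entered camera of limma 3.58.1 on log2 CPM, with a preset correlation between genes of 0.01 and adjustment over the 23 lists. Camera compares a list with all other tested genes. The lists were undifferentiated spermatogonia, differentiating spermatogonia, meiotic entry and prophase, pan-germ-cell, spermatid, Sertoli cell, Leydig cell, peritubular myoid cell, interstitial stroma, macrophage and leukocyte, endothelial cell, erythroid cell, rete testis and excurrent duct, p53 target, the CRL4-DCAF2 ligase and its substrates, DNA replication, mitosis, DNA damage response and repair, DNA methylation and demethylation, retinoic acid pathway, apoptosis, cholesterol synthesis, and immediate-early and stress. Some genes stand in more than 1 list. The named genes were also fixed by rule beforehand. Part a took Dtl, Cdkn1a, Tdg, Kmt5a, Cdt1, Gfra1, Zbtb16, Kit, Stra8, Sycp3, Ddx4 and Sox9. Part b took the 5 higher and 5 lower genes with the largest log2 fold changes among those past the threshold, with a mean log2 CPM of at least 1 and no overlap between the groups, passing over predicted genes. Part c took the 2 tested members with the smallest p of each list. Some genes that these rules take are not reported here.

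Simulated counts for 3 against 3 libraries, drawn from the means of the real genes, tested the procedure on 14291 genes. Of the genes changed by 0.58, 1 and 2 on the log2 scale, 49.3%, 92.5% and 100% were recovered. Of 171 calls, 10 were of unchanged genes. Of 200 lists drawn at random, 4 had a camera p under 0.05; these simulated genes vary independently of each other, unlike real genes.

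Alternatives chosen before the data were examined were DESeq2 1.42.0, limma-voom, RLE, upper-quartile and total-count scaling, scaling by the pan-germ-cell genes only, no filter and a stricter filter (CPM of at least 1 in at least 3 libraries), the replicate number as a block, each library left out in turn, 2 fold thresholds, and for lists an estimated correlation and fry, a rotation test. Alternatives added after seeing the data removed a trend on transcript length or on GC content from each library (lowess, span 0.3), and combined the length trend with leaving out control library 1 and the scaling by pan-germ-cell genes with leaving out each library or, for lists, with an estimated correlation. Leaving out a library makes its group smaller and the test less powerful, so a call can be lost while the size of the change stays similar. Length and GC were those of the longest GENCODE vM21 transcript of a gene ID, found for 99.9% of tested genes. In a simulation, the same length trend was put into all knockout libraries, and changed genes were drawn without regard to length. Unchanged genes called fell from 453 to 13 with the correction, and changed genes called from 163 to 156. In the data, control libraries 1 and 2 had opposite trends, so the simulation does not show how well the correction works here. Figures were drawn with matplotlib 3.10.9. All 6 libraries and both groups were used. Reads were not analysed here.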

Results

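The data are messenger RNA counts from whole mouse testes labelled day 9, where the labels do not say from which event days were counted. Of the 6 libraries, 3 came from controls and 3 from mice in which floxed Dcaf2 was deleted with Stra8-Cre, a Cre recombinase driven in spermatogonia. DCAF2 is the substrate receptor of the CRL4 ubiquitin ligase, which marks proteins such as p21 and thymine DNA glycosylase (TDG) for degradation. The study asked whether DCAF2 is needed for spermatogenesis, and its title names p21 and TDG as targets. The control libraries held 18372964, 17888720 and 16097362 counts and the knockout libraries 15634944, 17564942 and 15407007. A count above 0 was found for 16992, 17041 and 17010 genes in the controls and for 16700, 16743 and 16701 in the knockouts.

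The transcript of Dcaf2, listed under its current symbol Dtl (ENSMUSG00000037474), was at 56.7 ± 18.3 CPM in controls and 45.7 ± 5.15 CPM in knockouts (mean ± SD, n = 3 each), a log2 fold change of -0.31 (SE 0.202, 95% interval -0.77 to 0.14, edgeR adjusted p = 0.281). The groups overlapped, with 42.6, 50.3 and 77.4 CPM in the controls and 41.7, 43.8 and 51.5 CPM in the knockouts. Without control library 1, which had the lowest control level, the difference was -0.51 and passed the threshold (edgeR adjusted p = 0.0321), and without control library 3 it was -0.02 (adjusted p = 0.923). Whole-gene counts do not separate transcripts that lack the deleted part, and whole testes hold somatic cells in which Cre is not expected, so these values check the labels only loosely. Relative to pan-germ-cell genes, the Dtl transcript was higher in the knockouts, by 1.18 on the log2 scale, where the median of all genes was 1.49.

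Of 4 substrates of the ligase that were fixed by name, 1 passed the threshold at the transcript level. The ligase acts on proteins, so transcript levels do not show whether the proteins of these genes built up in the knockouts. Cdkn1a, which encodes p21 (ENSMUSG00000023067), was at 6.12 ± 0.203 CPM in controls and 8.38 ± 1.21 CPM in knockouts, higher in each knockout library than in any control, but its log2 fold change of 0.45 (SE 0.17) did not pass the threshold (edgeR adjusted p = 0.0821). It passed once the trend on transcript length was removed, at 0.52 (adjusted p = 0.0448, an alternative chosen after seeing the data). Tdg (ENSMUSG00000034674), which encodes a base excision repair enzyme, had 91.8 ± 4.46 and 92.3 ± 3.01 CPM, a difference of 0.01 with a 95% interval of -0.19 to 0.21. Kmt5a (ENSMUSG00000049327), a histone H4 methyltransferase gene, differed by 0.14 (SE 0.101, edgeR adjusted p = 0.326). Cdt1 (ENSMUSG00000006585), whose product licenses replication origins, fell from 54.7 ± 5.78 to 38.5 ± 5.66 CPM, a log2 fold change of -0.51 (SE 0.129, edgeR adjusted p = 0.0215). This call was lost without control library 3 (-0.49, adjusted p = 0.0776), knockout library 1 (-0.49, adjusted p = 0.0912) or knockout library 2 (-0.41, adjusted p = 0.103). It was the 1 member that passed among 13 tested members of the list of the ligase and its substrates, also when adjusted over the list alone. Without control library 1 or 2 there were 3 such members, and 0 without control library 3 or knockout library 1 or 2. The list had a median of -0.09 (0.01 without control library 2 and -0.04 without knockout library 1) and did not pass the list test (camera adjusted p = 0.504).

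**Figure D1:**
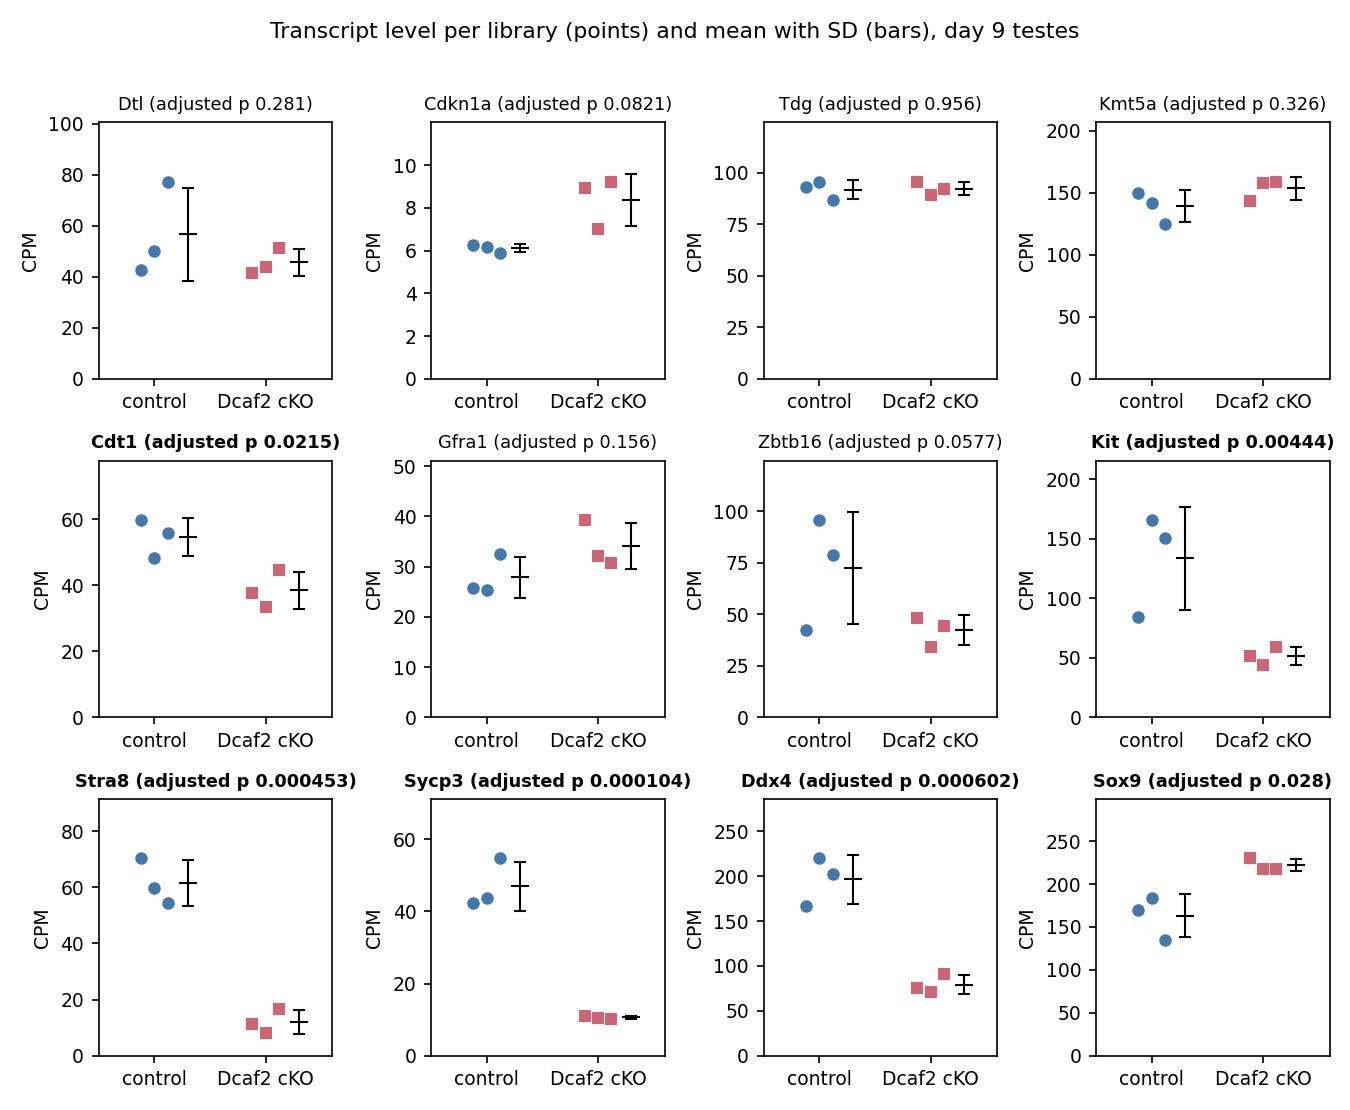
Transcript levels of the 12 genes fixed by name, with CPM on the vertical axis of each panel, circles for the 3 control libraries, squares for the 3 Dcaf2 knockout libraries and bars for mean ± SD; bold titles mark an edgeR adjusted p under 0.05. Stra8, Sycp3, Ddx4 and Kit lie lower in each knockout library than in any control (Kit and Ddx4 turn to 0.13 and 0.17 on the log2 scale once scaled to the pan-germ-cell genes), whereas the groups overlap for Dtl, Tdg, Kmt5a, Gfra1 and Zbtb16.

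Across the transcriptome, 3607 of 14424 tested genes differed between knockout and control testes, with 1599 higher and 2008 lower in the knockouts (edgeR, adjusted p under 0.05). Increases were small, with a median log2 fold change of 0.51, and decreases reached further, with a median of -0.69. At least 2-fold, 671 genes were lower and 82 higher, and at least 4-fold, 136 were lower and 2 higher. The groups did not overlap for 6440 tested genes (44.6%, where chance gives 10%). The count at an unadjusted p under 0.05 was 5636. With total-count scaling the split was 1109 higher and 2424 lower, and with scaling by the pan-germ-cell genes, which set changes relative to germ-cell transcripts, it was 13402 higher and 102 lower. The number of changed genes was 1795 without control library 3, 1444 without knockout library 1, 1355 without knockout library 2 and 1933 without knockout library 3. It was 5255 and 4277 without control library 1 or 2. A smaller group lowers the power of the test.

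Among genes with a standard symbol, a mean log2 CPM of at least 1 and no overlap between the groups, 4 of the 5 that fell furthest stand in the lists of differentiating spermatogonia or meiosis, and Steap1 in none. Some genes outside these limits fell further than members of the 5, such as Ly6k, with a mean log2 CPM of 0.87 (-4.83, edgeR adjusted p = 0.0016). Ins2 was at -4.94 (edgeR adjusted p = 0.0157), but its groups overlapped. It had 786, 1019 and 15 counts in the controls and 12, 19 and 20 in the knockouts, so its difference rests on control libraries 1 and 2. Ly6k and Ins2 were named after their values were seen. Esx1, an X-linked homeobox gene, fell from 17.9 ± 4.39 to 0.377 ± 0.163 CPM, 46.2-fold (log2 fold change -5.53, SE 0.328, edgeR adjusted p = 0.000104). Prss50, a testis serine protease gene, fell 23.8-fold, and Dmrtb1, a transcription factor gene of the passage from spermatogonial divisions to meiosis, 22.7-fold, from 47.0 ± 5.21 to 2.06 ± 0.612 CPM. Meioc, needed to keep cells in meiotic prophase, fell 12.5-fold, and Steap1, a metalloreductase gene, 8.8-fold. Among the genes that rose most were Minar1 (4.35-fold, from 2.36 ± 0.343 to 10.3 ± 3.11 CPM, edgeR adjusted p = 0.00131), Serpina12, a serpin gene (4.14-fold), the potassium channel gene Kcnh1 (3.45-fold) and Rimbp2, a synaptic scaffold gene (3.29-fold).

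Most tested genes of 3 germ-cell lists fell. All 24 tested members of the pan-germ-cell list were lower, also when adjusted over the list alone, with a median of -1.38 (camera adjusted p = 9.57e-19; adjusted p = 0.251 with an estimated correlation). Ddx4, an RNA helicase gene of the whole germ line, fell from 196 ± 26.8 to 79.2 ± 10.3 CPM (log2 fold change -1.31, SE 0.135), Tex13b fell by 1.84 on the log2 scale, and Tdrkh, of the piRNA pathway, fell by 1.47. Of 23 differentiating spermatogonia genes, 21 fell and 1 rose (22 and 1 adjusted over the list alone), with a median of -1.64 (camera adjusted p = 1.8e-15; adjusted p = 0.251 with an estimated correlation). Kit, the receptor of differentiating spermatogonia, fell from 134 ± 43.5 to 51.5 ± 7.28 CPM (edgeR adjusted p = 0.00444). Stra8, induced by retinoic acid before meiosis, fell 5.12-fold and Ddx25 3.94-fold. The member that rose was Ccnd2, a D-type cyclin gene, by 0.77 (edgeR adjusted p = 0.00251), named after its value was seen. Of 42 genes of meiotic entry and prophase, 33 fell and 0 rose (37 fell adjusted over the list alone), with a median of -1.59 (camera adjusted p = 4.11e-20; adjusted p = 0.251 with an estimated correlation). Sycp3, of the synaptonemal complex, fell from 47.0 ± 6.74 to 10.6 ± 0.401 CPM, and M1ap, of meiosis I, fell 4.88-fold. Scaled to the pan-germ-cell genes, 3 differentiating genes were higher and 10 lower (median -0.18), and 8 meiotic genes were higher and 9 lower (median -0.09). Kit and Ddx4 were then at 0.13 and 0.17 (edgeR adjusted p = 0.499 and 0.274).

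Undifferentiated spermatogonia genes were mixed. Of 29 tested, 13 fell and 2 rose (14 and 3 adjusted over the list alone), with a median of -0.54 (camera adjusted p = 0.000763; adjusted p = 0.555 with an estimated correlation). Sox3, a transcription factor gene of progenitor spermatogonia, fell 5.46-fold (from 33.8 ± 3.52 to 6.19 ± 0.684 CPM), and Egr4 fell 2.98-fold. Gfra1, the GDNF co-receptor gene of the stem-cell fraction, was at 27.9 ± 4.13 and 34.1 ± 4.61 CPM (log2 fold change 0.29, edgeR adjusted p = 0.156). With scaling by the pan-germ-cell genes Gfra1 was at 1.77 (edgeR adjusted p = 1.8e-06), where the median of all genes was 1.49. Zbtb16, a gene of undifferentiated spermatogonia, was at 72.4 ± 27.2 and 42.2 ± 7.22 CPM (-0.78, edgeR adjusted p = 0.0577); it passed without control library 1 (-1.07, adjusted p = 0.000319), and with DESeq2, upper-quartile or total-count scaling, no filter or the length trend removed. The 2 members that rose were Lhx1, by 1.05 (edgeR adjusted p = 0.0149), and Etv5, a GDNF-responsive gene, by 0.33 (adjusted p = 0.0321), named after their values were seen; without control library 3 or knockout library 3 only 1 member rose, and without knockout library 1 or 2 there were 0. Scaled to the pan-germ-cell genes, which raised the median of all genes by 1.46, the direction turned: 17 members were higher and 4 lower, with a median of 0.92. Of the spermatid list, 5 of 20 genes were tested and 0 passed, also at an unadjusted p and with DESeq2 or limma-voom (edgeR, median -0.40, camera adjusted p = 0.504). The median was -0.24, -0.07 and -0.14 without control library 1, control library 2 or knockout library 2. Izumo1 had 0.736 ± 0.161 and 0.481 ± 0.0994 CPM and Spaca1 1.29 ± 0.397 and 0.979 ± 0.256 CPM.

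**Figure D2:**
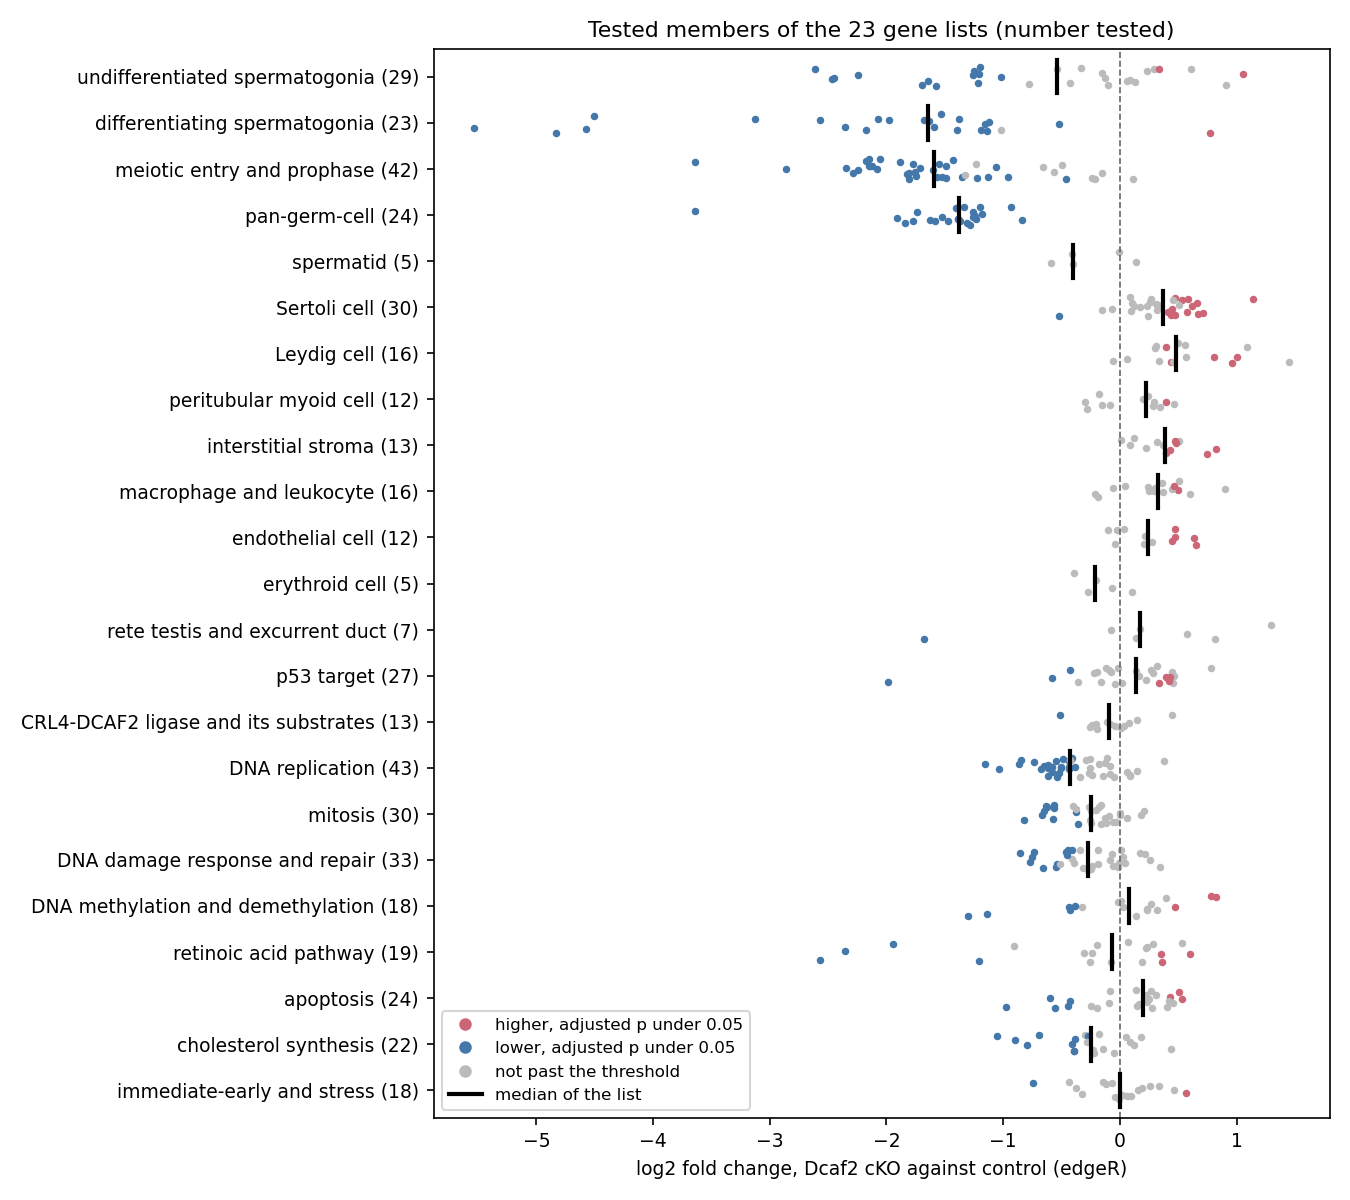
Log2 fold change of knockout against control (horizontal axis) for the tested members of each of the 23 lists, with the number tested in brackets; points are genes, coloured where the edgeR adjusted p was under 0.05, and black bars are medians. The medians of the differentiating, meiotic and pan-germ-cell lists lie at -1.64, -1.59 and -1.38, those of the Sertoli, Leydig and stroma lists at 0.37, 0.48 and 0.39. Scaled to the pan-germ-cell genes, the pan-germ-cell median is 0.11 and that of all genes 1.49. The lists of undifferentiated spermatogonia, spermatids, erythroid cells, the ligase, retinoic acid, replication, mitosis, DNA damage and cholesterol synthesis then have medians above 0 but below 1.49.

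Some markers of somatic cells were higher, and in each of the 6 lists of Sertoli, Leydig, stroma, macrophage, endothelial and myoid cells more members did not pass than rose (16, 10, 7, 14, 7 and 11). Of 30 Sertoli cell genes, 13 rose and 1 fell (16 and 1 adjusted over the list alone), with a median of 0.37 (camera adjusted p = 0.000337; adjusted p = 0.56 with an estimated correlation). Kitl, the ligand of KIT, rose from 396 ± 44.3 to 628 ± 33.9 CPM (edgeR adjusted p = 0.00382), and Sox9, the Sertoli cell fate gene, from 163 ± 25 to 222 ± 6.98 CPM (adjusted p = 0.028). The Sox9 call was lost without control library 3 or any 1 knockout library, where its adjusted p was 0.0823 to 0.106. The member that fell was Dmrt1 (-0.53, SE 0.0856), which spermatogonia also express and which is in the differentiating list too. Of 16 Leydig cell genes, 6 rose, also adjusted over the list alone, with a median of 0.48, and 0.80 without control library 1 (camera adjusted p = 0.000776; adjusted p = 0.56 with an estimated correlation); Prlr rose 1.95-fold and the steroidogenic enzyme gene Hsd17b3 1.75-fold. Of 13 stroma genes, 6 rose (8 adjusted over the list alone), with a median of 0.39 (camera adjusted p = 0.000776; adjusted p = 0.555 with an estimated correlation). Pdgfra rose 1.77-fold and Igf1 1.68-fold. The call on the stroma list was lost once the length trend was removed (camera adjusted p = 0.067), and those on all 3 lists with scaling by the pan-germ-cell genes (0.578, 0.79 and 0.19).

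Of 16 macrophage and leukocyte genes, 2 rose, Mrc1 by 0.50 and Cx3cr1 by 0.47 (1 adjusted over the list alone), with a median of 0.33, and 0.21 without control library 2 (camera adjusted p = 0.0131; adjusted p = 0.56 with an estimated correlation). Of 12 endothelial genes, 5 rose, also adjusted over the list alone, Pecam1 by 0.48 and Kdr by 0.63 among them, with a median of 0.24 (camera adjusted p = 0.0304; adjusted p = 0.56 with an estimated correlation). Without control library 2 both lists lost the call (camera adjusted p = 0.128 and 0.21), and the endothelial list lost it also without knockout library 3 (0.0798) or the length trend (0.0645). The endothelial median moved little in these settings, to 0.22, 0.21 and 0.22. Scaled to the pan-germ-cell genes, the camera adjusted p was 0.79 and 0.342. The Cx3cr1 call was lost without control library 2 or 3 or knockout library 1 or 2, and also with upper-quartile or total-count scaling or the length trend removed. Those of Pecam1 and Kdr were lost without knockout library 1 or 2. Of 12 peritubular myoid genes, 1 rose, Smtn by 0.39, also adjusted over the list alone. The list median was 0.22 (camera adjusted p = 0.504, fry adjusted p = 0.0267). It was 0.13 without control library 1 and 0.09 with the length trend removed. Mylk had 313 ± 28.5 and 382 ± 6.92 CPM (edgeR adjusted p = 0.0581, and 0.0247 without control library 2). The Smtn call was lost without control library 3 (adjusted p = 0.0504), knockout library 1 (0.0546) or knockout library 2 (0.076), and without control library 2 the list had 3 higher genes and 1 lower. Of 5 erythroid genes 0 passed with edgeR, also at an unadjusted p and with DESeq2 or limma-voom (median -0.21, camera adjusted p = 0.987). After scaling to the pan-germ-cell genes 4 of them were higher, with a median of 1.17 that lay under the 1.49 of all genes, and the list passed downward against other genes with the preset correlation (camera adjusted p = 0.0293; adjusted p = 0.929 with an estimated correlation). The globin genes varied between controls, with 2976, 1038 and 671 counts of Hba-a1 in control libraries 1, 2 and 3 and 85.1 ± 62.9 against 65.0 ± 27 CPM by group. Hbb-bs had 166 ± 117 and 137 ± 43.3 CPM, and without control library 1 the log2 fold changes of the 2 genes turned from -0.39 to 0.38 and from -0.27 to 0.44, with a list median of 0.48. That median was -0.53 without control library 3 and -0.56, 0.03 and -0.03 without knockout library 1, 2 or 3. Of 7 genes of the rete testis and ducts, 1 fell, also adjusted over the list alone, and 0 without knockout library 1 or 3, and the median was 0.17 (camera adjusted p = 0.728), against 0.48 and 0.39 without control library 1 or 3 and 0.26, 0.26 and 0.36 without knockout library 1, 2 or 3; Krt19 was at 0.857 ± 0.373 and 2.11 ± 1.45 CPM (edgeR adjusted p = 0.11).

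These somatic counts moved with single libraries, and a smaller group also lowers the power of the test. With any 1 library left out, the Sertoli median was 0.31 to 0.48, the Leydig median 0.36 to 0.80 and the stroma median 0.32 to 0.45. The macrophage and endothelial medians were then 0.21 to 0.40 and 0.21 to 0.30. Without control library 1, 24 Sertoli, 14 Leydig, 8 stroma, 4 macrophage and 5 endothelial genes were higher. Without control library 3 the counts were 6, 3, 6, 1 and 3, without knockout library 1 they were 4, 4, 2, 1 and 0, without knockout library 2 they were 3, 3, 3, 1 and 1, and without knockout library 3 they were 7, 3, 3, 2 and 2. Without control library 2 the macrophage count was 1. Leydig cell genes also differed between controls: Cyp17a1, which encodes an enzyme of androgen synthesis, was at 200, 32.9 and 20.2 CPM in control libraries 1, 2 and 3 and at 258, 241 and 193 CPM in the knockouts (log2 fold change 1.45, SE 0.693, edgeR adjusted p = 0.153; 3.09 and adjusted p = 4.77e-06 without control library 1). Star was at 150, 52.8 and 25.6 CPM in the controls and at 158, 191 and 139 CPM in the knockouts (edgeR adjusted p = 0.142). These 2 genes were chosen after their values were seen.

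Part of the genes of DNA synthesis, division and repair fell, while 20 of 43 replication, 20 of 30 mitosis and 22 of 33 damage genes did not pass. Of 43 DNA replication genes, 23 fell and 0 rose (25 and 1 adjusted over the list alone), with a median of -0.43 (camera adjusted p = 1.09e-07; adjusted p = 0.56 with an estimated correlation). Rfc4, of the clamp loader, fell from 39.4 ± 4.32 to 21.7 ± 1.5 CPM (edgeR adjusted p = 0.00199) and the helicase factor gene Cdc45 from 54.7 ± 3.53 to 30.4 ± 4.55 CPM. Of 30 mitosis genes, 10 fell, also adjusted over the list alone, with a median of -0.25, and -0.15 without knockout library 1 (camera adjusted p = 0.000763; adjusted p = 0.563 with an estimated correlation); the kinetochore gene Ndc80 fell by 0.65 and cyclin B1 (Ccnb1) fell by 0.63. Of 33 genes of the DNA damage response and repair, 11 fell (12 adjusted over the list alone), with a median of -0.27, and -0.46 without control library 1 (camera adjusted p = 0.00187; adjusted p = 0.56 with an estimated correlation). Fanci, of the Fanconi anaemia pathway, fell by 0.85 and the exonuclease gene Exo1 fell by 0.66. Replication, mitosis and damage genes that fell numbered 29, 12 and 19 without control library 1, 11, 5 and 7 without control library 3, 10, 5 and 5 without knockout library 1, 8, 5 and 5 without knockout library 2 and 20, 9 and 7 without knockout library 3. Scaled to the pan-germ-cell genes, 42, 30 and 33 members of these lists were higher and 0 lower, and the camera calls were lost (adjusted p = 0.686, 0.957 and 0.79). The list medians were then 1.05, 1.22 and 1.22, below the 1.49 of all genes.

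Of 27 genes in the fixed p53 target list, 4 rose and 3 fell, also adjusted over the list alone. The median was 0.14 (camera adjusted p = 0.504). It was 0.06 and 0.02 without control library 2 or 3 and 0.05 and 0.03 without knockout library 2 or 3. The members with the smallest p fell. Cdkn2a, which encodes the inhibitor p16 and p19ARF, went from 16.4 ± 1.25 to 4.14 ± 0.505 CPM (edgeR adjusted p = 0.000219). The nuclease gene Aen fell by 0.58. A place in this fixed list does not show that p53 controls a gene, and the fall of Cdkn2a is not a measure of p53 activity. Higher and lower members of the p53 target list numbered 5 and 5 without control library 1, 0 and 2 without control library 3, knockout library 1 or knockout library 2, and 1 and 2 without knockout library 3. Of 24 apoptosis genes, 3 rose and 5 fell (6 and 5 adjusted over the list alone), with a median of 0.20 (camera adjusted p = 0.504). Bid fell by 0.55 and Diablo fell by 0.44, both encoding promoters of cell death. Among the higher members were the inhibitors of cell death Bcl2 and Cflar, named after their values were seen. Higher and lower apoptosis genes numbered 5 and 5 without control library 1, 0 and 3 without control library 3, 0 and 1 without knockout library 2, and 1 and 1 without knockout library 1 or 3. The Diablo call was lost without knockout library 1 (adjusted p = 0.0679) or 3 (0.0578), and the Bid call without knockout library 2 (0.0541).

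Of 22 cholesterol synthesis genes, 9 fell and 0 rose (11 and 1 adjusted over the list alone), with a median of -0.25 (camera adjusted p = 0.00194; adjusted p = 0.326 with an estimated correlation). Mvd fell from 33.6 ± 4.65 to 16.2 ± 1.66 CPM and Fdps from 99.7 ± 9.64 to 57.5 ± 3.97 CPM (edgeR adjusted p = 0.00173 and 0.00195). The number that fell was 4 without control library 3, knockout library 1 or knockout library 2. Scaled to the pan-germ-cell genes 21 were higher, with a median of 1.21 under the 1.49 of all genes, and the call was lost (camera adjusted p = 0.959). Of 18 genes of DNA methylation and demethylation, 3 rose and 5 fell, also adjusted over the list alone; the median was 0.08, the mean -0.02 and the camera direction up (adjusted p = 0.944). Without control library 1, 2 or 3 the median was 0.05, 0.13 and 0.05, and without knockout library 3 it was 0.01. The de novo methyltransferase gene Dnmt3b fell 2.2-fold (edgeR adjusted p = 0.00431), and Ung, of base excision repair, fell by 0.43. Among the higher members were Tet1 (0.82) and Tet2 (0.78), named after their values were seen. Without control library 3 or knockout library 1 or 2, 0 members were higher and 1 lower, without knockout library 3 they were 0 and 3, and without control library 2 they were 4 and 3. The Ung call was lost without control library 3 or knockout library 1 or 2 (adjusted p = 0.0663, 0.0764 and 0.0876). Of 19 retinoic acid pathway genes, 3 rose and 4 fell, also adjusted over the list alone, with a median of -0.07 and a mean of -0.38 (camera adjusted p = 0.504; with scaling by the pan-germ-cell genes 0.00337 with the preset correlation and adjusted p = 0.929 with an estimated correlation). The median turned to 0.05, 0.03 and 0.01 without control library 1, 2 or 3 and to 0.02 without knockout library 2. Without control library 1 there were 5 higher members, without control library 2 there were 2, and without any 1 of the other libraries 1; Crabp1, a retinoic acid binding protein gene, fell 5.94-fold and Rbp4 3.84-fold. Of 18 immediate-early and stress genes, 1 rose and 1 fell (0 and 1 adjusted over the list alone), with a median of 0 (-0.08 to 0.10 with 1 library left out) and a mean of -0.01, while the camera direction was up (adjusted p = 0.908). Atf3 fell by 0.75 and Egr2 rose by 0.56, and both calls were lost without control library 3, knockout library 1 or knockout library 2, that of Egr2 also without control library 2 or knockout library 3, or with upper-quartile or total-count scaling. Without control library 1 the list had 3 higher genes.

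The preset-correlation test thus put 13 of 23 lists past the threshold, and 0 of 23 passed with an estimated correlation, where 3 had an unadjusted p under 0.05. With an estimated correlation and scaling by the pan-germ-cell genes, a combination chosen after seeing the data that removes shared deviations of these genes by construction, the 4 lists of pan-germ-cell, meiotic and spermatogonial genes passed downward (camera adjusted p = 0.00058 to 0.0158). With fry, which does not compare a list with other genes, 9 passed. The Sertoli, Leydig, macrophage, endothelial, mitosis and DNA damage lists, which had passed the preset-correlation test, missed the threshold with fry (adjusted p = 0.0554 to 0.126). The myoid and retinoic acid lists, which had not passed that test, passed with fry (adjusted p = 0.0267 and 0.0154). The preset-correlation test also put 13 lists past the threshold in 2 other splits of the 6 libraries, which still hold part of the genotype difference. Libraries of the same group also differed. The first principal component of log2 CPM (56% of the variance) separated the groups, and the second (19.6%) spread the controls, at 37.0, -25.3 and -8.5 for libraries 1, 2 and 3, while the knockouts lay between -5.9 and 5.6. Control libraries 1 and 2 held 1387 and 1823 counts of 5 islet hormone genes against 17 in control library 3 and 14, 20 and 21 in the knockouts. By transcript length, in 10 bins of genes, the median deviation of control library 1 from its group mean went from 0.27 in the shortest bin to -0.32 in the longest, and that of control library 2 from -0.21 to 0.29. The median log2 fold change between the groups went from -0.17 to 0.25 over the same bins. Higher genes had a median transcript length of 4767 bases and lower genes of 2889 bases.

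**Figure D3:**
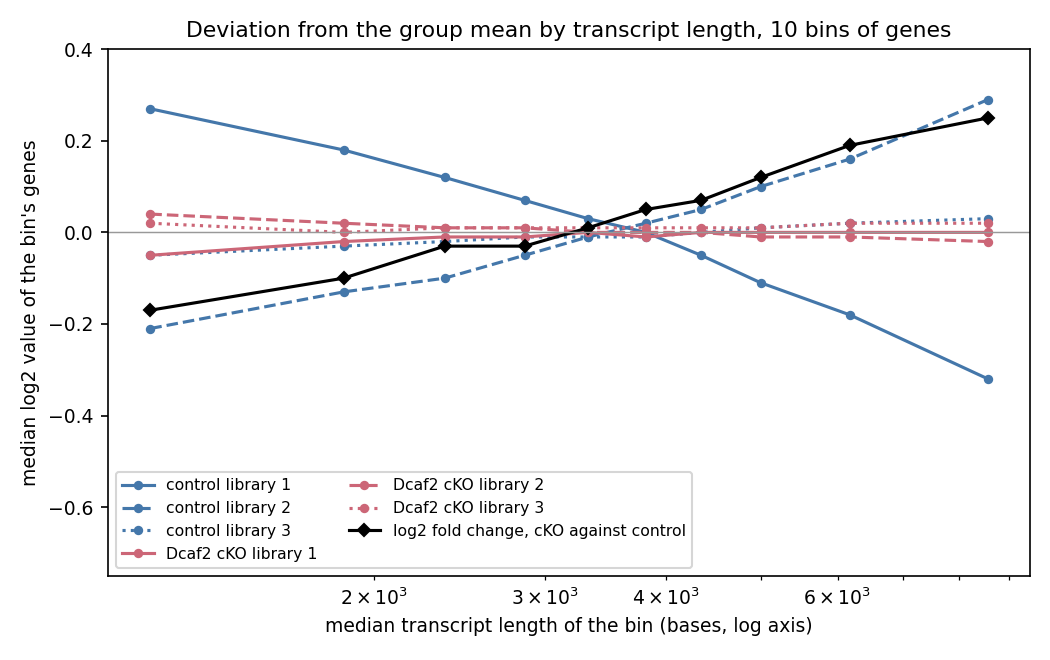
Median log2 deviation of each library from its group mean, and median log2 fold change of knockout against control (vertical axis), in 10 bins of genes by transcript length (horizontal log axis, bases). Control libraries 1 and 2 run in opposite directions, from 0.27 to -0.32 and from -0.21 to 0.29, the other 4 libraries stay between -0.05 and 0.04, and the fold change runs from -0.17 to 0.25.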

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

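The alternatives that removed a length or GC trend, or joined scaling by the pan-germ-cell genes with a library left out or an estimated correlation, were added after seeing the data, and all others were planned. In no setting other than scaling by the pan-germ-cell genes did a gene called higher or lower turn the other way. For named genes, 1031 of the comparisons with an alternative kept direction and side of the threshold, 45 lost the call, 16 gained one and 40 turned direction. For lists these numbers were 322, 38, 4 and 4. With any 1 library left out, changed genes numbered 1355 to 5255 (452 to 2392 higher, 903 to 2863 lower), and the Dtl change lay between -0.509 and -0.024. The cause was not tested. With the length trend removed and control library 1 left out, 5747 genes changed (2464 higher, 3283 lower) and Dtl was at -0.55. A fold threshold leaves fewer genes by construction: 753 at 2-fold or more (82 higher, 671 lower) and 395 by glmTreat against 0.58 (15 higher, 380 lower). The number of lists past the threshold was 6 with scaling by the pan-germ-cell genes, 0 with an estimated correlation and 4 with both.

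Scaling by the pan-germ-cell genes adds 1.46 to the median of all genes by construction and gave 13504 changed genes (13402 higher, 102 lower). Dtl was then at 1.18 and these genes turned from lower to higher: Cdt1 at 0.94, Zbtb16 0.73, Kit 0.13, Ddx4 0.17, Izumo1 0.88, Spaca1 1.03, Dmrt1 0.93, Hba-a1 0.98, Hbb-bs 1.10, Aen 0.87, Rfc4 0.59, Cdc45 0.62, Ndc80 0.82, Ccnb1 0.83, Fanci 0.63, Exo1 0.81, Dnmt3b 0.36, Ung 1.02, Bid 0.90, Diablo 1.02, Mvd 0.41, Fdps 0.66 and Atf3 0.71, with Tdrkh at 0.00. The lists of DNA damage and of cholesterol synthesis turned up with camera adjusted p = 0.79 and 0.959, and 0.999 for both with an estimated correlation. Tdg, near 0 in each setting but this scaling, was at -0.005 with DESeq2, -0.009 with RLE, -0.019 with upper-quartile and -0.058 with total-count scaling, -0.001 without a filter, -0.012 and -0.032 with the length and GC trends removed, -0.019 with the length trend removed and control library 1 left out, and -0.03 to 0.033 with 1 library left out. Hba-a1 lay between -0.78 and 0.38 and Hbb-bs between -0.61 and 0.44 with 1 library left out. They were at 0.45 and 0.50 without control library 1 and the length trend, and Hbb-bs at 0.07 without the trend. The cause was not tested.

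Libraries that share a replicate number did not deviate together (r across genes, which are not independent, of -0.07, -0.08 and 0.07), and not every library correlated best with its own number, control library 1 reaching 0.22 with knockout library 2. With the replicate block, 2822 genes changed (1248 higher, 1574 lower), 13 lists passed, Dtl was at -0.27 and Cx3cr1 and Egr2 lost their calls. At this depth and number of libraries, simulated changes of 0.58 on the log2 scale were recovered in 49.3% of genes, so smaller changes can be missed.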

Other observations

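All tests in this part other than the counts over splits of the libraries were chosen after the result was seen. Genes were grouped by symbol into 12 families, with 24 Fisher's exact tests adjusted together. All 10 tested Xlr genes, an X-linked lymphocyte-regulated family, were lower (median -1.47, one-sided adjusted p = 3.22e-08), as were 11 of 15 Tex genes (median -1.15, adjusted p = 2.36e-06) and 5 of 7 Rhox homeobox genes (median -1.54, adjusted p = 0.00411). These families did not pass camera with an estimated correlation (adjusted p = 0.0942, 0.137 and 0.156). Of 16 Mage genes, 6 were lower and 1 higher, short of the threshold (median -0.59, Fisher's exact adjusted p = 0.0569; camera adjusted p = 0.0209 with the preset and 0.156 with an estimated correlation). Scaled to the pan-germ-cell genes, the medians were 0 for Xlr, 0.32 for Tex, -0.09 for Rhox and 0.87 for Mage, so the direction turned for Tex and Mage. The median of all genes was then 1.49. Copies of Xlr, Rhox and Mage genes share reads, and their single values are uncertain.

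Of 42 collagen genes, 27 were higher and 1 lower (median 0.48, Fisher's exact adjusted p = 5.94e-15). Of 22 genes with an Adamts symbol, 11 were higher (median 0.42, Fisher's exact adjusted p = 3.97e-05). This group holds Adamts-like (Adamtsl) genes beside the Adamts protease genes, with Adamtsl1 among the higher ones (0.78). With an estimated correlation neither the collagen nor the Adamts group passed (camera adjusted p = 0.137 and 0.156). With the length trend removed 21 collagen genes were higher and 2 lower (median 0.30) and 9 genes with an Adamts symbol were higher (median 0.30). Of 380 Zfp genes, 60 were higher and 18 lower (median 0.14, Fisher's exact adjusted p = 0.0118; camera adjusted p = 0.418 with an estimated correlation), and with the length trend removed 62 were higher and 36 lower (median 0.08). Of 42 clustered protocadherin genes 7 were higher (adjusted p = 0.534). Genes of cytosolic ribosomal proteins (0 higher, 10 lower of 79), Nduf subunits (0 and 7 of 47), Hox factors (2 and 0 of 23) and the mitochondrial genome (0 and 0 of 13) had Fisher's exact adjusted p = 1 in both directions. With the preset correlation, camera put the protocadherin (median 0.66, adjusted p = 1.06e-06), ribosomal protein (median -0.30, 1.06e-06), Nduf (median -0.23, 0.000365) and Hox (median 0.26, 0.0217) families past the threshold. With an estimated correlation these were at 0.156, 0.52, 0.52 and 0.275. With the length trend removed, 11 protocadherin genes were higher (median 0.61), 4 ribosomal protein genes higher and 21 lower (median -0.15), 8 Nduf genes lower (median -0.09) and 6 Hox genes higher (median 0.31). Scaled to the pan-germ-cell genes the ribosomal protein and Nduf medians turned to 1.14 and 1.20, under the 1.49 of all genes.

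Control libraries 1 and 2 held transcripts of pancreatic islet hormones. Ins2 had 786 and 1019 counts there, 15 in control library 3 and 12, 19 and 20 in the knockouts, and Ins1, Gcg, Iapp and Sst followed, for 75.5 and 102 CPM in all against 1.06 in control library 3. Testis expression lost in the knockout stays open, since the low level of control library 3, at 1.19% of the mean of the other controls, is part of the pattern and rests on 1 library. Islet RNA or reads carried into these libraries stay open too, since the chi-square test of the 5 genes' counts (p = 0.0932) covers counting error only and a miss of the threshold does not show equal ratios. Among other islet genes, Scg2 (37 and 32), Ppy (17 and 22) and Pyy (13 and 13) had counts in these 2 libraries and 0 in the other 4, Chgb (41 and 33) and G6pc2 (18 and 30) had 1 to 8 and 1 to 3 there, Chga was at 152, 171 and 87 counts in the controls and 23, 25 and 32 in the knockouts (edgeR adjusted p = 0.00186), and Slc2a2 was at 23 to 41 throughout, while of 7 acinar genes Pnlip (32 and 21 against 11 in control library 3), Amy2a5 (8 and 15 against 3), Cela1 (13 and 9 against 3), Ctrb1 (5 and 10 against 0) and Prss2 (3 and 3 against 0) were higher in both libraries than in control library 3, and Cpa1 (8 and 8 against 9) and Try4 (3 and 1 against 2) were not.

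The 1599 genes higher in the knockouts were weighed against technical explanations. With the length trend removed, 83.7% stayed higher and past the threshold. How well this correction works here was not shown, so the length trend as the whole cause stays open. Control library 1 alone is argued against, since 94.1% of the higher genes stayed so without it. A lower share of germ-cell RNA, which would raise all other transcripts alike, stays open for 1558 of them. Their median was 0.5, beside medians of 0.22 to 0.48 for the 6 lists of Sertoli, Leydig, stroma, macrophage, endothelial and myoid cells. The erythroid list and that of the rete testis and ducts lay outside this range, at -0.21 and 0.17. These 1558 genes were selected for being higher and were not shown to exceed 0.48 by glmTreat. With 3 libraries per group, this does not show that they lie within 0.48. The other 41 (2.56%) exceeded 0.48 by glmTreat, Greb1, Esr2 and Pdgfra among them, too few to decide against the bound of 5% set for this test. The value of 0.48 is the median of the Leydig list, which was 0.80 without control library 1. Which genes exceed the somatic medians thus depends on that library. A change of expression in somatic cells of the knockout stays open and untested.

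With scaling by the pan-germ-cell genes, 10 of 23 differentiating spermatogonia genes were lower with edgeR, as were 8 of 41 meiotic genes, leaving out Meioc, which the pan-germ-cell list also holds, and 4 of 29 undifferentiated spermatogonia genes (Sox3, Upp1, Nanos3 and Neurog3), against 1 of 24 pan-germ-cell genes. With 1 library left out, these counts ran from 7 to 10, 5 to 10 and 2 to 4, against 1 to 3 pan-germ-cell genes. A loss of germ cells of unchanged make-up stays open: one-sided Fisher's exact adjusted p was 0.00496, 0.124 and 0.24 for these lists, but the scaling centres the pan-germ-cell genes, and any somatic RNA of theirs would make other germ-cell genes look lower. Leaving out control library 1 or knockout library 1 also put the first of these at 0.0581 and 0.0608, and the 72.4% of undifferentiated genes that differed lie below the 93.6% of all tested genes, which this scaling raises by construction. Expression in somatic cells may hold up the 17 undifferentiated genes that were higher, whose median change in the whole testis was 0.06, and whole-testis counts cannot decide this. Scaled in this way, the differentiating genes furthest below the pan-germ-cell genes were Esx1 (-4.04), Ly6k (-3.38), Prss50 (-3.08) and Dmrtb1 (-3.02). In that list 3 genes were higher, and its median was -0.18. A change in expression or make-up of the germ cells with genotype stays open and untested.

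The 6 libraries make 10 splits into 3 and 3, too few for a share under 0.05. The real split gave 3607 changed genes and the highest other split 2, so 1 of 10 splits gave as many. For the lists, 3 of 10 splits put as many past the threshold with the preset correlation, with 13 in the real split and 13 in the highest other. Those others set control library 1 with knockout libraries 1 and 2 or 1 and 3. Every split but the real one has unequal numbers of controls on its sides, so part of the genotype difference remains in it. A list moved by genotype can pass in such a split, so these counts do not measure chance alone.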
